A study of Mus musculus with 22 samples.

How the data were processed

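The 22 libraries were cochlear RNA of mice carrying a prestin-driven, tamoxifen-inducible Cre and a ribosomal protein Rpl22 that Cre tags with haemagglutinin. Per the labels' protocols, tamoxifen was given at 3 mg per 40 g of body weight to mice under 21 days old and at 9 mg per 40 g to older ones, ribosomes were pulled down with an antibody to the tag, and libraries were made with a directional kit. The dose changed with age, so that dose and age cannot be separated. The design text speaks of biological duplicates or triplicates, on which all p-values here rest. It names P21 where the labels name P28, and the labels were followed. Reads were aligned with TopHat (version not given) to GRCm38, per the submitters' processing notes. The tool that counted reads per gene, its version and whether it used the strand of the reads are not given in the sources used here. Reads of near-identical genes, of pseudogenes, and of overlapping or antisense genes therefore could not be told apart.

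The authors deposited 1 table per library with a CPM value per gene, scaled to the total of all reads in that table, as the column totals show. Each column summed to 1000000 over 49671 gene identifiers and 5 entries that name no gene, such as reads outside genes or aligned to several places. These 5 were kept out of all tests, and their shares are part of the results. Of the identifiers, 49326 had a symbol and 49412 were on the reference annotation, GENCODE M21. All values (100%) were whole multiples of the CPM of 1 read within a tolerance of 0.01, so that whole reads were recovered; 1 read was worth 0.0141 to 0.0325 CPM.

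Genes at a CPM of at least 1 in at least 2 libraries (18737) were tested on log2(CPM + 1), with CPM as deposited. Fold changes on this scale understate the change of genes with low values. limma 3.58.1 in R 4.3.3 fitted 1 mean for each of the 10 groups of age and fraction over all 22 libraries, with a trended prior, and tested 12 contrasts, two-sided. These were IP against input over all ages and at each age, IP at P14 against P8, P28 against P14, 10 weeks against P28 and 10 weeks against P8, input at 10 weeks against P8, and the change of enrichment from P8 to 10 weeks. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a contrast. Genes called at all 5 ages were counted. For 29 gene lists with 383 genes, 363 of them tested, camera was run with its preset correlation of 0.01, adjusted over the lists, and counts of called members were also taken from p-values adjusted over the list alone. List medians are relative to the median of all genes.

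The comparisons, lists and naming rule were fixed before the data were examined. The rule names, for the comparison over all ages, IP at 10 weeks against P8 and the change of enrichment, the 10 largest called log2 changes each way, and 5 each way otherwise. It takes genes with a mean CPM of at least 5 in the higher group, no predicted gene or pseudogene symbol, and all libraries of one side beyond all of the other within every age. It adds called members of the lists, and Slc26a5, Rpl22 and Ikzf2 in every comparison. Of the genes it names, 2 are not reported here. Alternatives fixed then were a pseudocount of 0.25, no filter on low values, TMM scaling, quantile normalization, removal of mitochondrial and haemoglobin genes, a fit of only the libraries compared, a replicate block, leaving out each library, and, for lists, an estimated correlation and fry. Count tests on the recovered reads with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 called 7665 and 8811 genes over all ages. Alternatives chosen after the data were seen were CPM over gene reads only, leaving out the 3 libraries with under 12000 genes at a CPM of at least 1 (P8 input 2, P14 IP 1 and P28 IP 2), and TMM scaling joined with that, with the block or with an estimated correlation.

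The procedure was tested on simulated reads with 100 genes changed 2-fold and 100 changed 4-fold. All simulated libraries shared the same mean profile and all genes the same dispersion, and changed genes had a mean CPM of at least 5. Libraries that stand apart were not imitated, so the rates hold for these settings and may overstate recovery in the real data. For the comparison over all ages, among 17795 genes, 93% of the 2-fold and 100% of the 4-fold changes were recovered. For 10 weeks IP against input (17785 genes) it recovered 14% and 92%, for IP at 10 weeks against P8 (17805 genes) 12% and 82%, and for the change of enrichment (17801 genes) 1% and 21%. For the microRNA tests, 3' untranslated regions of GENCODE M21 were searched for seed matches in 14693 of 14884 protein-coding genes (98.7%), with Python 3.11.15. A simulated search ranked the altered heptamer first in 5 of 5 runs. Coordinates are those of GRCm38, counted from 1.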

Results

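The libraries came from cochleae of mice in which outer hair cells, the electromotile sensory cells that amplify sound in the cochlea, carry an epitope-tagged ribosomal protein. Tamoxifen switches on a Cre recombinase made from the prestin locus (Slc26a5), and Cre adds a haemagglutinin tag to the ribosomal protein Rpl22. RNA bound to tagged ribosomes was pulled down with an antibody (IP libraries) and set beside RNA of the whole cochlea (input libraries) at P8, P14, P28, 6 weeks and 10 weeks. Each fraction had 2 libraries at every age but 10 weeks, which had 3, so that 11 IP and 11 input libraries made 22 in all. The files held CPM values for 49671 genes, each scaled to the library's total. Total reads per library ran from 30757875 to 49470561 in IP (median 39586316) and from 33170715 to 71023032 in input (median 47064448). Reads counted to genes ran from 14978013 to 39907763 per library.

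IP and input RNA differed in composition. Reads outside annotated genes made up 32.9 ± 8.74% (SD, n = 11) of the IP libraries and 13.3 ± 2.66% of the input libraries. Messenger RNAs encoded by the mitochondrial genome took 0.531 ± 0.202% of gene reads in IP and 3.98 ± 0.911% in input. Gm42418, an annotated gene that overlaps a copy of ribosomal RNA, took 58.3% of gene reads in P8 input replicate 2, 18.6% in 6wk input replicate 2 and 10.2% in P14 IP replicate 1. The 10 genes with most reads held 73.7% of gene reads in P8 input replicate 2, whose median gene stood at 0.117 times its value in replicate 1. The first principal component, with 28.3% of the variance, placed all 11 IP libraries on one side and all 11 input libraries on the other. P28 IP replicate 2 stood apart on the second (13.7% of the variance), at -121.0 where the others ran from -33.6 to 76.2, and had the fewest genes detected, 14357. Replicates of a group correlated across genes with a Pearson r of 0.792 (P28 IP) to 0.989 (10wk input replicates 1 and 2); genes are not independent replicates.

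**Figure D1:**
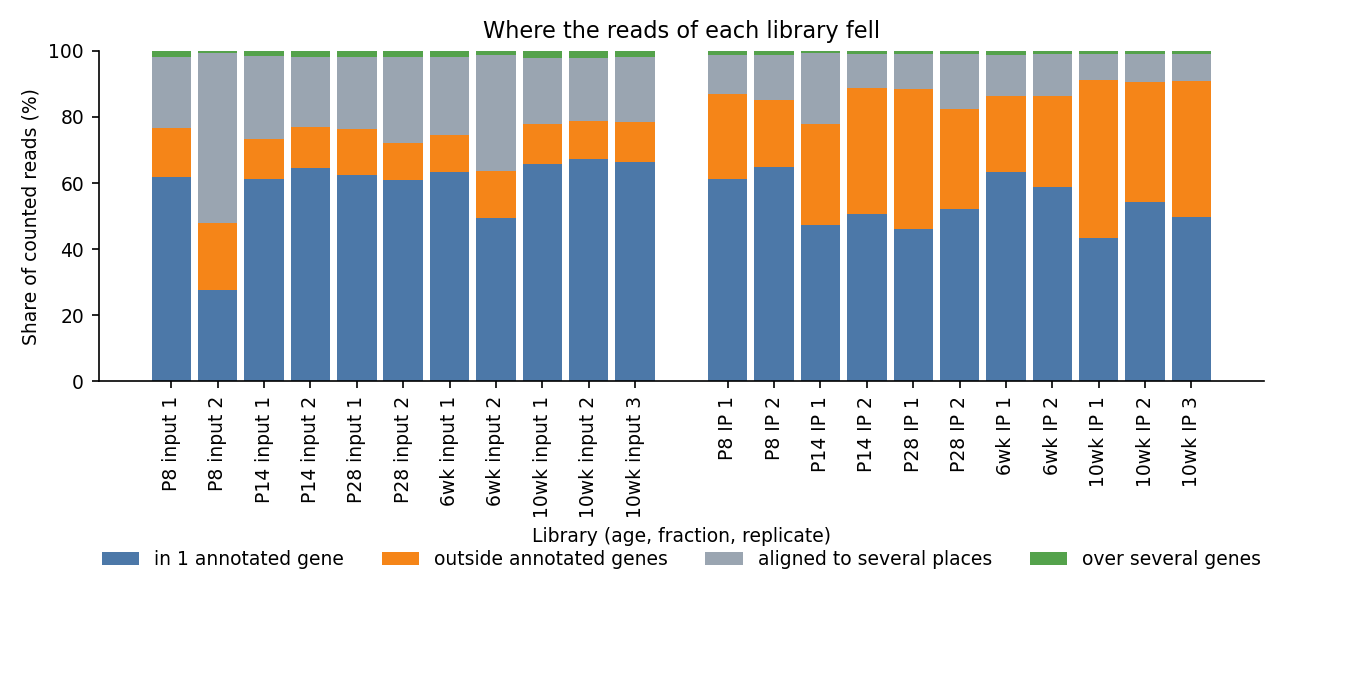
Percent of reads in each of the 22 libraries that were counted to genes, lay outside genes, were ambiguous or aligned to several places. Reads outside genes take 20.2% to 47.7% of the IP libraries and 11.1% to 20.4% of the input libraries.

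Ikzf2 (ENSMUSG00000025997; chromosome 1, 69531214 to 69687245 on GRCm38), a transcription factor of outer hair cells, was higher in every IP library than in every input library of its age. Its mean over the IP libraries was 52.3 ± 17.4 CPM (SD, n = 11) against 8.08 ± 2.79 CPM in input, a log2 change of 2.48 relative to the median of all genes (SE 0.33, limma adjusted p = 2.42e-09). Ocm (chromosome 5, 144019804 to 144026670), the calcium-binding protein oncomodulin of outer hair cells, was at 288 ± 146 CPM in IP and 53.4 ± 31.7 CPM in input (log2 2.31, SE 0.30, limma adjusted p = 1.59e-09). Slc26a5 (ENSMUSG00000029015; chromosome 5, 21810655 to 21865604), which encodes prestin and carries the Cre in these mice, was at 19.97 ± 8.33, 2.33 ± 1.97, 3.60 ± 2.82, 5.80 ± 8.12 and 35.8 ± 17.8 CPM in IP at P8, P14, P28, 6 weeks and 10 weeks. In input it was at 1.92 ± 2.06, 3.28 ± 1.01, 5.38 ± 7.18, 4.05 ± 1.85 and 6.40 ± 0.418 CPM. Over all ages the Slc26a5 difference did not pass the limma test (log2 0.74, SE 0.43, adjusted p = 0.111). Rpl22 (ENSMUSG00000028936; chromosome 4, 152325742 to 152334071), the tagged protein's gene, was at 40.6 ± 10.1 CPM in IP and 77.0 ± 30.7 CPM in input, which did not pass either (log2 -0.79, SE 0.31, adjusted p = 0.0906). With trimmed-mean (TMM) scaling Rpl22 passed the test, with a log2 change of -0.89 (limma adjusted p = 8.94e-06).

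**Figure D2:**
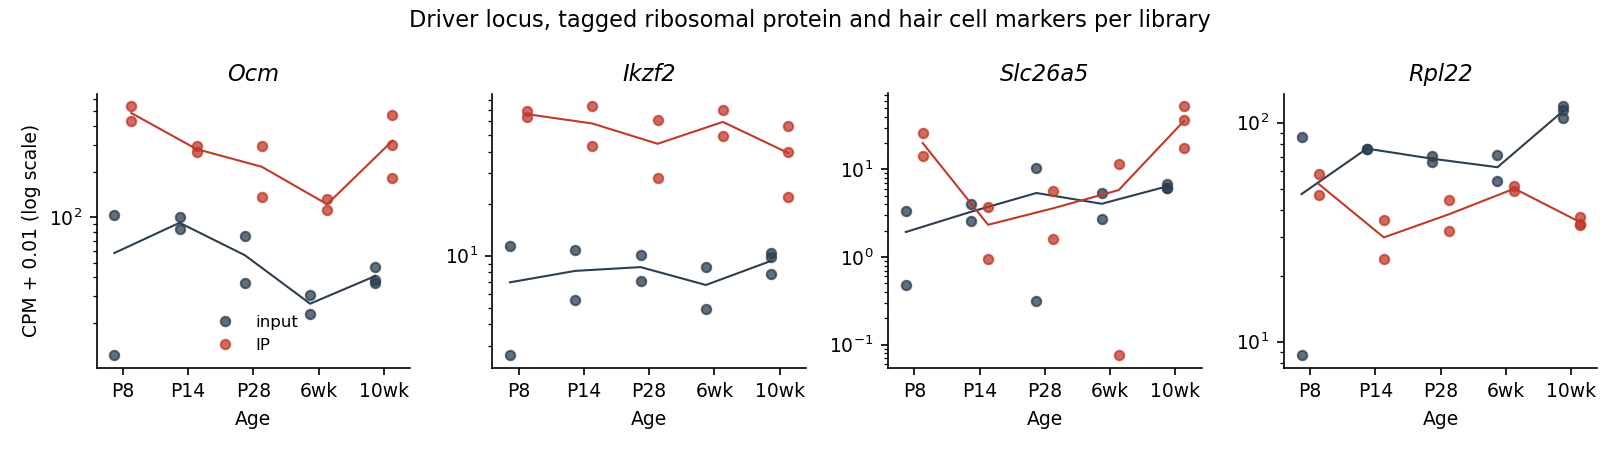
CPM of Ocm, Ikzf2, Slc26a5 and Rpl22 in each library, by age, with IP and input apart and a line through the group means. Ocm and Ikzf2 lie higher in IP than in input at all 5 ages, while Slc26a5 values overlap at P14, P28 and 6 weeks.

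Averaged over the 5 ages, Hic2 and Tnrc6a were the RNAs most enriched in IP of all genes tested. Other genes named as highest or lowest, here and in each comparison below, are ranked among those with a mean of at least 5 CPM in the higher group, no predicted gene or pseudogene symbol, and no overlap of libraries within an age. Hic2 (chromosome 16, 17233572 to 17263430), a transcriptional repressor, was at 164 ± 70.8 CPM in IP against 4.58 ± 2.87 CPM in input, 28.9-fold higher on the log2(CPM + 1) scale. Tnrc6a (chromosome 7, 123123885 to 123195296), a GW182 protein that binds Argonaute, was at 2093 ± 898 against 81.2 ± 37.3 CPM. The others of the 10 largest increases in that ranking were Arid3a, Igdcc3, Prtg, Nr6a1, Plagl2, Lmbr1l, Tnrc6c and Kcnq1ot1, an imprinted noncoding RNA, with log2 changes relative to all genes of 3.95 (Kcnq1ot1) to 4.47 (Arid3a). Lowest in IP was mt-Co1, cytochrome c oxidase subunit 1 of the mitochondrial genome, at 376 ± 160.0 CPM against 7244 ± 3376 CPM in input. The mitochondrial ribosomal RNAs mt-Rnr2 (-3.85) and mt-Rnr1 (-3.24) followed in that ranking, with Qpct, Ifi27l2a, Wfdc18, Ndufaf8, Ebp and Uchl1 from -3.15 (Qpct) to -2.21 (Uchl1). In each of these 19 genes all IP libraries lay on one side of all input libraries within every age. The largest limma adjusted p among Hic2, Tnrc6a and mt-Co1 was 1.97e-13, for mt-Co1. Of 18737 genes tested, 3747 were higher and 2340 lower in IP by limma at an adjusted p under 0.05. The median gene was 0.13 higher in IP, so changes are given relative to it; p-values are those of the changes as deposited, tested against 0. With TMM scaling, which takes that shift away, 3875 were higher and 4334 lower, and 5808 genes were called in the same direction under both scalings. More genes were lower than higher with quantile normalization (4229 and 4566), the block and TMM scaling (3985 and 4432) and edgeR (3732 and 3933), higher first, and without P8 input 2.

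Many hair cell genes were enriched in IP. Of the outer hair cell markers, 9 of 15 tested were higher (median log2 1.08 relative to all genes), among them Chrna10 (2.03), a subunit of the efferent acetylcholine receptor, and Bcl11b (1.91). Of hair cell transcription factors, 10 of 19 were higher, such as Rfx7 (2.16), Isl1 (1.58) and Pou4f3 (1.23). Markers shared by inner and outer hair cells gave 9 of 15 higher and 1 lower, with Rbm24 (1.91) and the actin bundler Espn (1.6) higher and the calcium buffer Pvalb (-1.40) lower. Mechanotransduction and stereocilia genes gave 9 of 24 higher, such as Strc (2.26), Fscn2 (1.36) and Myo15 (1.36), and hair cell channels and synapse genes 6 of 14, with Chrna9 (1.47), Bsn (1.40) and Cacna1d (1.16). Inner hair cell markers went both ways, with Tbx2 (1.26) higher and Atp2a3 (-1.32) and Rprm (-1.23) lower, and the list did not pass (median -0.18, adjusted p = 0.46; 1 higher and 2 lower when adjusted over the list alone). For outer hair cell markers the list test gave adjusted p = 5.39e-05 (adjusted p = 0.288 with an estimated correlation), with 11 higher when adjusted over the list alone. For transcription factors the list test gave adjusted p = 6.04e-05 (adjusted p = 0.363 with an estimated correlation), with 12 higher when adjusted over the list alone. For the shared markers the list test gave adjusted p = 0.0194 (adjusted p = 0.492 with an estimated correlation), with 12 higher and 1 lower when adjusted over the list alone. For mechanotransduction genes the list test gave adjusted p = 0.0116 (adjusted p = 0.531 with an estimated correlation), with 10 higher when adjusted over the list alone. For channels and synapse the list test gave adjusted p = 0.0194 (adjusted p = 0.448 with an estimated correlation), with 6 higher when adjusted over the list alone. None of these 5 lists kept an adjusted p under 0.05 with an estimated correlation.

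Many markers of blood and other cochlear cells were lower in IP. Neutrophil and myeloid precursor markers gave 9 of 10 lower, such as S100a8 (-2.21) and Ngp (-2.05). Erythroid markers gave 7 of 9 lower, such as haemoglobin Hbb-bs (-1.79), which shares sequence with Hbb-bt, and macrophage markers 6 of 10, such as Lyz2 (-1.71). The stria vascularis list, from the tissue that makes endolymph, gave 7 of 12 lower, with Dct (-1.86) and Kcne1 (-1.67), and Bsnd higher (1.44). Spiral ganglion neuron markers gave 4 of 12 lower, with Calb2 (-1.54), Thy1 (-1.35) and Snap25 (-1.32), and Prox1 higher (1.39). Fibrocyte and mesenchyme markers gave 5 of 12 lower and 1 higher, with Dcn (-2.0) and Otos (-1.67) lower, and Schwann cell markers 2 of 11 lower, S100b (-1.33) and Cnp (-0.91). Supporting cell markers gave 4 of 16 lower and 2 higher, with Ceacam16 (-1.35) and Gjb6 (-1.09) lower, and did not pass as a list (adjusted p = 0.213; 2 higher and 4 lower when adjusted over the list alone). Bone and cartilage markers did not pass either (adjusted p = 0.0751; 1 higher and 4 lower when adjusted over the list alone), with 4 of 12 lower and 1 higher, among them Spp1 (-2.16) lower and Runx2 (1.45) higher. For neutrophil markers the list test gave adjusted p = 6.79e-06 (adjusted p = 0.247 with an estimated correlation), with 9 lower when adjusted over the list alone. For erythroid markers the list test gave adjusted p = 0.000673 (adjusted p = 0.247 with an estimated correlation), with 7 lower when adjusted over the list alone. For macrophage markers the list test gave adjusted p = 0.000673 (adjusted p = 0.282 with an estimated correlation), with 8 lower when adjusted over the list alone. For stria vascularis the list test gave adjusted p = 0.00141 (adjusted p = 0.492 with an estimated correlation), with 1 higher and 7 lower when adjusted over the list alone. For spiral ganglion neurons the list test gave adjusted p = 0.0103 (adjusted p = 0.448 with an estimated correlation), with 1 higher and 4 lower when adjusted over the list alone. For fibrocytes and mesenchyme the list test gave adjusted p = 0.0159 (adjusted p = 0.579 with an estimated correlation), with 1 higher and 5 lower when adjusted over the list alone. For Schwann cells the list test gave adjusted p = 0.0259 (adjusted p = 0.58 with an estimated correlation), with 1 lower when adjusted over the list alone.

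Energy metabolism genes were low in IP and nuclear RNAs high. Of nuclear-encoded oxidative phosphorylation genes, 20 of 21 were lower, such as Ndufa1 (-2.58) and Cox4i1 (-2.10), and of mitochondrially encoded mRNAs 7 of 9, with mt-Cytb (-2.82) and mt-Nd5 (-2.78). Cytosolic ribosomal protein genes, many of which share reads with processed pseudogenes, gave 14 of 34 lower and 2 higher, with Rpl32 (-2.75) and Rps14 (-2.65) lower. Oxidative stress defence genes gave 9 of 14 lower, such as Prdx1 (-1.95) and catalase, Cat (-1.94). Interferon response genes gave 4 of 10 lower, with Ifi27 (-1.77) and Bst2 (-1.73). RNAs that stay in the nucleus or are not translated gave 8 of 9 higher, with Xist (2.72), Malat1 (1.84) and Snhg11 (1.59). The share of reads outside genes was higher in IP alongside these RNAs, by 18.7 percentage points averaged over ages (exact permutation test within ages, two-sided p = 0.000154, n = 11 and 11). Fetal and neonatal growth genes gave 9 of 11 higher and 1 lower, with Sox11 (3.48), H19 (3.14), Igf2bp2 (2.84) and Igf2 (2.28) higher. Calcium buffering and homeostasis genes did not pass as a list (adjusted p = 0.0848; 3 higher and 7 lower when adjusted over the list alone), with 6 of 16 lower, such as S100a1 (-1.99), and 2 higher. For oxidative phosphorylation the list test gave adjusted p = 7.86e-16 (adjusted p = 0.247 with an estimated correlation), with 21 lower when adjusted over the list alone. For mitochondrially encoded mRNAs the list test gave adjusted p = 1.23e-10 (adjusted p = 0.131 with an estimated correlation), with 8 lower when adjusted over the list alone. For ribosomal proteins the list test gave adjusted p = 5.15e-07 (adjusted p = 0.406 with an estimated correlation), with 3 higher and 14 lower when adjusted over the list alone. For oxidative stress defence the list test gave adjusted p = 7.90e-06 (adjusted p = 0.363 with an estimated correlation), with 9 lower when adjusted over the list alone. For interferon response genes the list test gave adjusted p = 0.0194 (adjusted p = 0.448 with an estimated correlation), with 1 higher and 5 lower when adjusted over the list alone. With TMM scaling it no longer passed (adjusted p = 0.0558). For nuclear and untranslated RNAs the list test gave adjusted p = 2.15e-06 (adjusted p = 0.0056 with an estimated correlation), with 8 higher when adjusted over the list alone. With TMM scaling and an estimated correlation this list did not pass (adjusted p = 0.0924). For fetal growth genes the list test gave adjusted p = 1.04e-06 (adjusted p = 0.247 with an estimated correlation), with 10 higher and 1 lower when adjusted over the list alone.

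**Figure D3:**
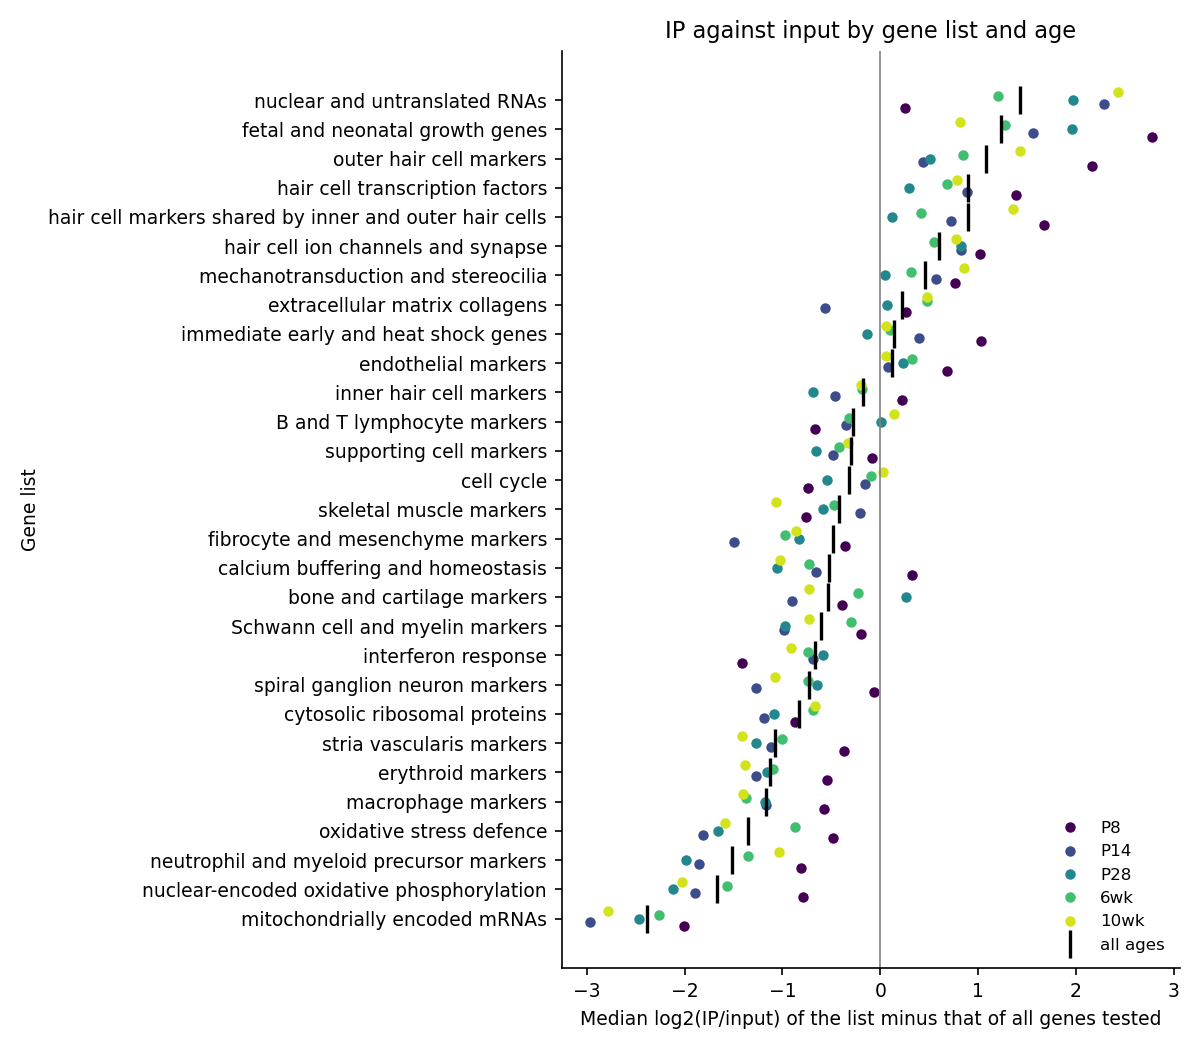
Median log2 change of each fixed gene list in IP against input, relative to all genes, in log2(CPM + 1) units. Points show each age and ticks the comparison over all ages. Over all ages, mitochondrially encoded mRNAs lie lowest in IP against input (-2.38) and nuclear and untranslated RNAs highest (1.43).

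At P8, before the onset of hearing, Tnrc6a, Tnrc6b, the imprinted growth-related RNA H19, Igdcc3 and Arid3a were the most enriched in IP. H19 was at 17358 ± 262 CPM (SD, n = 2) in IP and 426 ± 499 CPM in input, a log2 change of 5.44 relative to the median of all genes (limma adjusted p = 7.43e-08), and Tnrc6a was at 2459.5 ± 326 and 40.6 ± 40.7 CPM (5.61, adjusted p = 4.86e-08). The mitochondrial ribosomal RNAs mt-Rnr2 (-5.00) and mt-Rnr1 (-4.43), Qpct (-3.93), Mir6236 (-3.37; with TMM scaling adjusted p = 0.0579) and keratocan, Kera (-2.7), were the lowest. Ikzf2 was at 66.1 ± 3.57 CPM in IP against 6.998 ± 6.17 CPM (2.59, adjusted p = 0.00191). Slc26a5 was at 19.97 ± 8.33 against 1.92 ± 2.06 CPM (2.25, adjusted p = 0.0374; with TMM scaling 0.156). Rpl22 was at 52.5 ± 8.47 against 47.2 ± 54.5 CPM (0.14, adjusted p = 0.486), and its log2 change as deposited, 0.88, turned to -0.52 with TMM scaling. By limma 2179 genes were higher and 7 lower in IP. The median gene was 0.74 higher in IP as deposited, and with TMM scaling 1164 were higher and 961 lower. Leaving out 1 library gave a count of 8746 without P8 input 1, 1048 without P8 IP 1, 797 without P8 input 2 and 489 without P8 IP 2. limma called 0 genes in a fit of only the libraries compared (622 at an unadjusted p under 0.05) and 1298 without a filter, and on all libraries edgeR called 1711 and DESeq2 3043. More genes were lower than higher with quantile normalization (1442 and 1544), the low-yield libraries out (750 and 1033), these out and TMM scaling (1119 and 1258) and DESeq2 (1478 and 1565).

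At P14, around the onset of hearing, Zcchc3, Hic2, Tnrc6a, Prtg and Igdcc3 were the most enriched in IP. Zcchc3 was at 284 ± 63.2 CPM (SD, n = 2) in IP and 7.56 ± 2.13 CPM in input (log2 5.33 relative to all genes, limma adjusted p = 9.58e-05). The lowest were mt-Co1 (-4.37), the enolase copy Eno1b (-3.72), which shares sequence with Eno1, pancreatic-type ribonuclease Rnase1 (-3.59), Tspo (-3.52) and mt-Cytb (-3.49). Ikzf2 was at 58.4 ± 21.8 CPM against 8.15 ± 3.72 CPM (2.98, adjusted p = 0.0307). Slc26a5 was at 2.33 ± 1.97 against 3.28 ± 1.01 CPM (-0.21, adjusted p = 0.849) and Rpl22 at 29.9 ± 8.42 against 76.2 ± 0.0724 CPM (-1.07, adjusted p = 0.271). The test called 321 genes higher and 494 lower in IP, where the median gene was -0.28; with TMM scaling 1892 were higher and 1622 lower. The count of both came to 19 without P14 input 1, 46 without P14 IP 1 and 117 without P14 input 2. At this age limma called 0 genes in a fit of only the libraries compared (3353 at an unadjusted p under 0.05) and 94 without a filter, and on all libraries edgeR called 2566 and DESeq2 4156. More genes were higher than lower with no filter (58 and 36), the block and TMM scaling (1980 and 1673), CPM over gene reads (803 and 691), edgeR (1531 and 1035) and DESeq2 (2412 and 1744), and without P14 input 1, P14 IP 1 or P14 input 2.

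In P28 mice the transcription factors Pou2f2, Hic2, En2 and Arid3a and the membrane protein gene Igdcc3 were the most enriched. Pou2f2 was at 66.7 ± 26.4 CPM (SD, n = 2) in IP and 0.364 ± 0.0564 CPM in input (log2 5.60 relative to all genes, limma adjusted p = 0.000123). Nhp2 (-5.12), a protein of small nucleolar particles, the complex I subunit Ndufs6 (-4.96), mt-Co1 (-4.59) and the ribosomal protein genes Rpl32 (-4.58) and Rpl7a (-4.57) were the lowest. Ikzf2 was at 44.5 ± 23.0 against 8.57 ± 2.10 CPM (2.19, adjusted p = 0.0627; with TMM scaling 0.00184), Slc26a5 at 3.60 ± 2.82 against 5.38 ± 7.18 CPM (0.13, adjusted p = 1), and Rpl22 at 38.2 ± 8.79 against 68.5 ± 3.09 CPM (-0.82, adjusted p = 0.49). The mean Slc26a5 value was lower in IP while its mean log2 value was higher, since input replicate 2 stood at 0.301 CPM. The numbers called were 593 higher and 968 lower, and 1833 and 2372 with TMM scaling. Single libraries moved the total to 2798 without P28 IP 1, 669 without P28 input 2 and 834 without P28 IP 2. For P28 limma called 0 genes in a fit of only the libraries compared (2628 at an unadjusted p under 0.05) and 387 without a filter, and on all libraries edgeR called 3276 and DESeq2 6042. More genes were higher than lower with CPM over gene reads (1313 and 1137), TMM scaling and the low-yield libraries out (2653 and 2480) and DESeq2 (3092 and 2950), and without P28 IP 2.

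In young adults of 6 weeks Hic2, Tnrc6a, Prtg, the orphan nuclear receptor Nr6a1 and Zcchc3 were the most enriched in IP. Hic2 was at 200.2 ± 32.6 CPM (SD, n = 2) in IP and 3.61 ± 2.35 CPM in input (log2 5.27 relative to all genes, limma adjusted p = 3.47e-05). The lowest were mt-Co1 (-4.61), mt-Rnr2 (-4.58) and mt-Rnr1 (-3.86). Ikzf2 was at 59.6 ± 14.4 against 6.75 ± 2.62 CPM (2.72, adjusted p = 0.0262). Slc26a5 was at 5.80 ± 8.12 against 4.05 ± 1.85 CPM (-0.68, adjusted p = 0.946), with IP replicates at 11.5 and 0.0655 CPM. Rpl22 was at 49.99 ± 1.64 against 62.6 ± 11.9 CPM (-0.57, adjusted p = 0.943). There were 236 genes called higher and 5 lower, with a median gene 0.27 higher in IP, and with TMM scaling 794 higher and 818 lower. The count became 59 without 6wk input 1, 36 without 6wk IP 1, 15 without 6wk input 2 and 20 without 6wk IP 2. It was 1975 in a fit of only the libraries compared and 146 without a filter. More genes were lower than higher with quantile normalization (1205 and 1308), the block and TMM scaling (824 and 883) and TMM scaling and the low-yield libraries out (1323 and 1791).

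At 10 weeks, the age with 3 libraries per fraction, the noncoding RNAs Kcnq1ot1 and Lncpint and the genes Tnrc6a, Nr6a1 and Hic2 were the most enriched. Kcnq1ot1 was at 556 ± 220.4 CPM (SD, n = 3) in IP and 30.0 ± 9.14 CPM in input (log2 4.12 relative to all genes, limma adjusted p = 1.90e-06); it lies antisense to Kcnq1. The lowest were mt-Co1 (-4.56), Wfdc18 (-3.49), mt-Rnr2 (-3.45), the interferon-induced Ifi27l2a (-3.44) and Rnase1 (-3.32). Slc26a5 was higher in all 3 IP libraries than in any input library, at 35.8 ± 17.8 against 6.40 ± 0.418 CPM, but did not pass (2.19, adjusted p = 0.113; with TMM scaling 0.0489). Ikzf2 was at 39.4 ± 17.4 against 9.33 ± 1.35 CPM (1.88, adjusted p = 0.0664; with TMM scaling 0.00168) and Rpl22 at 35.2 ± 1.61 against 113 ± 7.21 CPM (-1.64, adjusted p = 0.0844; with TMM scaling 0.000122). In all 337 genes were higher and 452 lower, and with TMM scaling 1218 and 1765. Fits that left out a library called 96 without 10wk input 1, 340 without 10wk IP 1, 146 without 10wk input 2, 213 without 10wk IP 2, 155 without 10wk input 3 and 141 without 10wk IP 3. The number was 7503 in a fit of only the libraries compared. More genes were higher than lower with no filter (405 and 243), CPM over gene reads (1387 and 515) and DESeq2 (1689 and 1616), and without 10wk IP 1 or 10wk IP 2.

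Across the 5 ages, 38 genes were called higher in IP at every age and 2, the mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2, were called lower at every age. If the ages were independent, 0.000268 genes would be expected among the higher and 6.14e-08 among the lower. The ages share 1 estimate of the spread for each gene, so their calls are linked and these numbers are no test. The 38 included Hic2, Tnrc6a, Tnrc6b, Tnrc6c, Arid3a, Igdcc3, Prtg, Nr6a1, Plagl2, Zcchc3, Lmbr1l, Kcnq1ot1 and Sox11. With TMM scaling 288 genes were higher and 356 lower at every age, by edgeR 301 and 284, and by DESeq2 519 and 450. Without a filter on low values limma gave 7 and 0, and in fits of only the libraries compared 0 and 0. The 2 are mitochondrial genes, so that none was left with those removed. Leaving out 1 of the libraries in turn moved the 38 by over 1.5 times for 14 libraries, to between 5 (without 10wk IP replicate 2) and 260 (without P8 input replicate 1), and the 2 to between 0 (without P14 input replicate 1) and 173 (without P8 input replicate 2).

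The age comparisons within IP ask how RNA in the IP libraries changed with age. They do not show in which cells a change took place, and the change in whole cochlear RNA is given further below. From P8 to P14, Ceacam16, a glycoprotein of the tectorial membrane, rose from 3.60 ± 3.11 to 188 ± 91.9 CPM (SD, n = 2 at each age), a log2 change of 5.84 relative to all genes (limma adjusted p = 5.96e-08). Slc4a11, a membrane transporter of spiral ligament fibrocytes, rose from 7.88 ± 4.64 to 313 ± 52.1 CPM, and the noncoding RNA Snhg11 (4.87), Csmd1 (4.66) and the calcium channel gene Cacna1a (4.59) rose as well. H19 fell from 17358 ± 262 to 381 ± 210.5 CPM (adjusted p = 1.76e-06), with Tectb (-4.76), encoding beta-tectorin of the tectorial membrane, Espnl (-4.51), an espin-like protein of stereocilia, Igf2 (-4.42) and Ubtf (-3.97), a factor for transcription of ribosomal RNA genes. Slc26a5 (-2.36, adjusted p = 0.137), Rpl22 (-0.43, 0.62) and Ikzf2 (0.15, 0.95) did not pass. By limma 160 genes were higher and 202 lower at P14, where the median gene was -0.38, and with TMM scaling 1049 were higher and 515 lower. The count was 70 without P14 IP 1, 925 without P14 IP 2 and 47 without P8 IP 2. For this step limma called 0 genes in a fit of only the libraries compared (2381 at an unadjusted p under 0.05) and 174 without a filter, and on all libraries edgeR called 973 and DESeq2 2362. More genes were higher than lower with a pseudocount of 0.25 (75 and 63), quantile normalization (814 and 624), the block and TMM scaling (948 and 421), CPM over gene reads (294 and 198), TMM scaling and the low-yield libraries out (839 and 581), edgeR (795 and 178) and DESeq2 (1645 and 717), and without P14 IP 1.

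From P14 to P28 the genes that rose most in IP were the formin Fhod3 (3.66), Klhl3 (3.60), ceramide synthase Cers1 (3.56), the adhesion gene Cadm3 (3.52) and Zdhhc23 (3.45). Cadm3 went from 5.38 ± 5.19 to 59.7 ± 14.3 CPM (SD, n = 2 at each age; limma adjusted p = 0.00674). Rarres1 fell most, from 105 ± 69.3 to 4.62 ± 6.48 CPM (log2 -4.85, adjusted p = 0.00139), followed by Dram2 (-3.75), the inhibitor of NF-kappaB signalling Tnfaip3 (-3.73), Arhgap45 (-3.71) and Tmem198 (-3.64). Slc26a5 (0.46, adjusted p = 0.956), Rpl22 (0.35, 0.946) and Ikzf2 (-0.43, 0.926) did not pass. There were 50 genes higher and 106 lower at P28, and with TMM scaling 455 higher and 759 lower. Single libraries moved the count to 13 without P14 IP 1, 662 without P14 IP 2 and 1535 without P28 IP 1. Between P14 and P28 limma called 0 genes in a fit of only the libraries compared (424 at an unadjusted p under 0.05) and 38 without a filter, and on all libraries edgeR called 414 and DESeq2 2383. More genes were higher than lower with TMM scaling and the low-yield libraries out (109 and 101), and without P14 IP 2 or P28 IP 2.

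From P28 to 10 weeks Armcx3 (3.54), Tmtc4 (3.40), Zfp777 (3.33), Ube2q2 (3.29) and the Mediator subunit Med24 (3.27) rose most in IP relative to all genes. Tmtc4 went from 3.83 ± 5.09 CPM (SD, n = 2) to 42.6 ± 12.97 CPM (n = 3; limma adjusted p = 0.0024). Mir6236 (-6.07), the potassium channel gene Kcnk3 (-3.94), osteocalcin Bglap (-3.72), which shares reads with Bglap2, Pou2f2 (-3.57) and type I collagen Col1a1 (-3.56) fell most. Col1a1 was at 156 ± 21.4 CPM at P28 and 15.9 ± 3.997 CPM at 10 weeks (adjusted p = 0.00181). Slc26a5 was at 3.60 ± 2.82 and 35.8 ± 17.8 CPM (2.7, adjusted p = 0.0588), and neither Rpl22 (-0.42, 0.973) nor Ikzf2 (-0.49, 0.946) passed. At 10 weeks 308 genes were higher and 68 lower, with a median gene of 0.32, against 688 and 609 with TMM scaling. The count changed to 50 without 10wk IP 1, 87 without 10wk IP 2, 80 without 10wk IP 3, 2369 without P28 IP 1 and 52 without P28 IP 2. From P28 on limma called 0 genes in a fit of only the libraries compared (3585 at an unadjusted p under 0.05), 173 with the replicate block and 654 with the block and TMM scaling, and on all libraries edgeR called 660 and DESeq2 2641. More genes were lower than higher with the block and TMM scaling (317 and 337), TMM scaling and the low-yield libraries out (382 and 468) and edgeR (227 and 433), and without P28 IP 2.

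Over the whole span from P8 to 10 weeks, growth and matrix genes fell in IP. H19 (chromosome 7, 142575529 to 142578143) fell from 17358 ± 262 CPM (SD, n = 2) to 38.3 ± 27.6 CPM (n = 3), 613-fold lower on the log2(CPM + 1) scale as deposited (log2 -9.31 relative to all genes, SE 0.71, limma adjusted p = 1.39e-16). Col2a1 (chromosome 15, 97975602 to 98004695), the main cartilage collagen, fell from 12818 ± 1727 to 46.0 ± 9.17 CPM (-8.15, adjusted p = 2.39e-15). Tectb (-7.13), the growth factor gene Igf2 (-6.19), C1qtnf1 (-6.04), bone sialoprotein Ibsp (-5.80), Mir6236 (-5.22), Tmprss9 (-5.06), Cpz (-5.05) and Ccn4 (-4.91) completed the 10 largest decreases ranked, which leave out predicted genes. Slc4a11 (chromosome 2, 130684113 to 130697519) rose from 7.88 ± 4.64 to 727 ± 119 CPM, 87.3-fold as deposited (log2 6.40 relative to all genes, SE 0.64, adjusted p = 5.96e-12). Snhg11 (6.02), Neat1 (4.96), the RNA scaffold of nuclear paraspeckles, Ceacam16 (4.94), the carnosinase gene Cndp1 (4.38), Csmd1 (4.23), the interferon-induced Ifit3 (4.16) and the chromatin remodeller Chd5 (4.08) also rose. Lncpint and Amy1, which shares sequence with other amylase genes, had no reads in either P8 IP library and stood at 26.3 ± 6.95 and 17.7 ± 3.51 CPM at 10 weeks. In each of these genes all 3 libraries of 10 weeks lay on one side of both P8 libraries. Slc26a5 (0.69, adjusted p = 0.745), Rpl22 (-0.60, 0.725) and Ikzf2 (-0.88, 0.592) did not pass. By limma 418 genes were higher and 403 lower at 10 weeks, and with TMM scaling 951 and 1186, with 774 genes called under both; CPM over gene reads gave 1121 higher and 414 lower. Leaving out libraries gave 336 without 10wk IP 1, 465 without 10wk IP 3, 485 without P8 IP 1 and 137 without P8 IP 2. The span gave 1381 in a fit of only the libraries compared. More genes were lower than higher with quantile normalization (1549 and 1561), only the libraries compared (669 and 712), the replicate block (255 and 302), the block and TMM scaling (710 and 974), the low-yield libraries out (1787 and 1980) and edgeR (556 and 873), and without 10wk IP 3, P8 IP 1 or P8 IP 2.

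**Figure D4:**
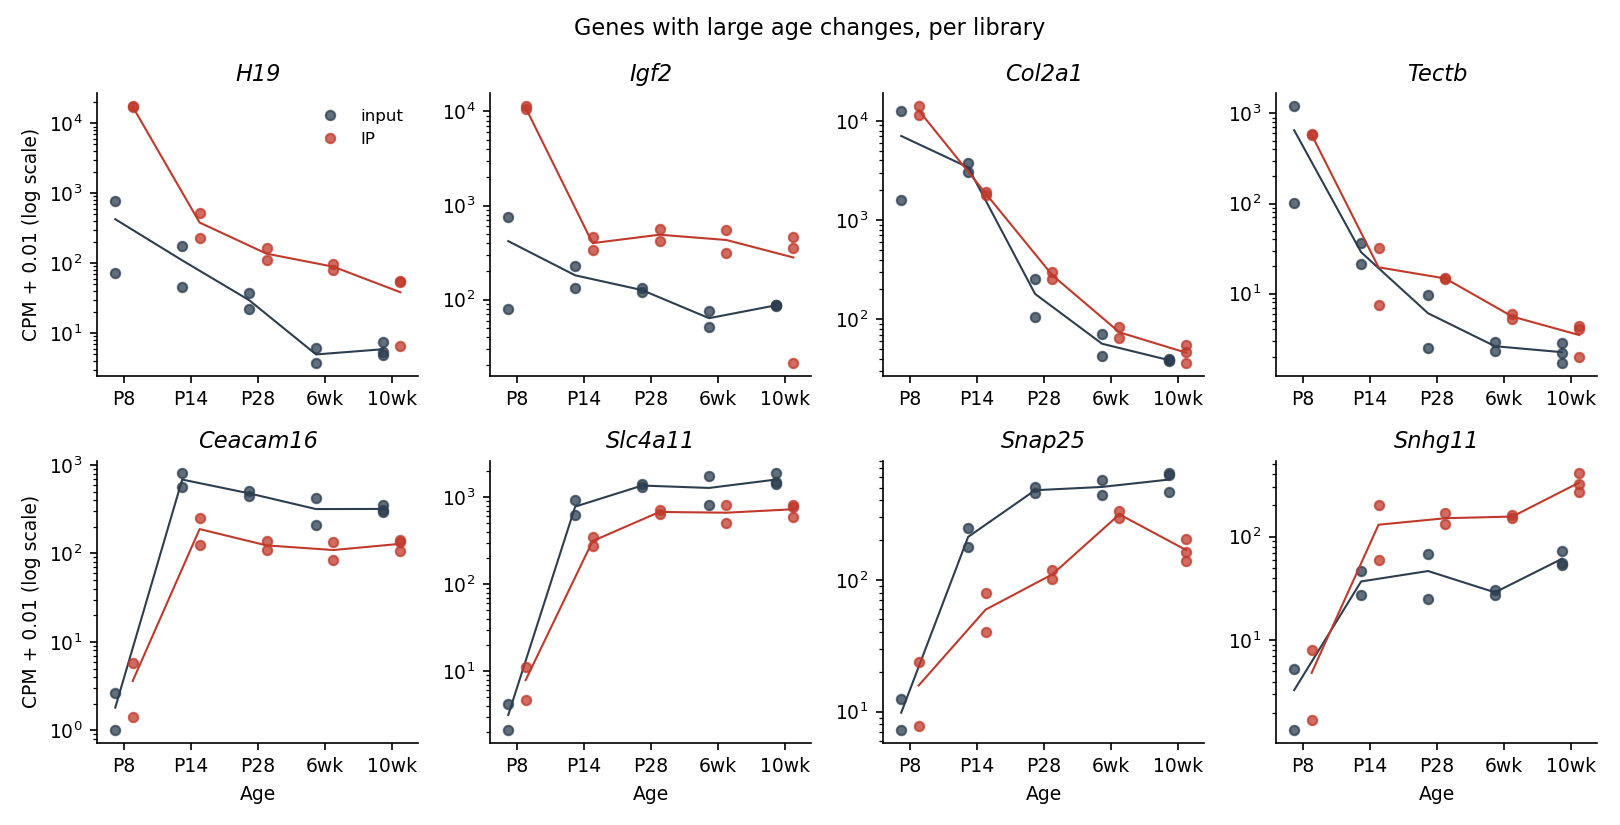
CPM on a log axis of H19, Igf2, Col2a1, Tectb, Ceacam16, Slc4a11, Snap25 and Snhg11 in each IP and input library by age. H19 in IP goes from 17358 ± 262 CPM at P8 to 38.3 ± 27.6 CPM at 10 weeks.

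Among the fixed lists, 11 of 15 extracellular matrix collagens were lower in IP at 10 weeks than at P8, such as Col3a1 (-4.76), Col1a1 (-4.66) and Col1a2 (-4.58). Bone and cartilage markers gave 8 of 12 lower and 1 higher, with Sp7 (-4.31) and Bglap (-3.58) lower. Fetal and neonatal growth genes gave 7 of 11 lower, with Igf2bp1 (-4.01) and Sox4 (-3.89), and fibrocyte and mesenchyme markers 6 of 12 lower and 1 higher. Spiral ganglion neuron markers gave 5 of 12 higher, with the synaptic protein gene Snap25 (3.46) and the neurofilament genes Nefh (3.01) and Nefl (2.65). Interferon response genes gave 4 of 10 higher, such as Bst2 (3.77) and Ifit1 (3.30). Nuclear and untranslated RNAs gave 4 of 9 higher, such as Rn7sk (3.58) and Miat (3.47). Reads outside genes took 20.2% and 25.9% of the P8 IP libraries and 36.0% to 47.7% of those of 10 weeks. Few hair cell genes were called: Lmod3 (-3.76) of the outer hair cell markers and Calb1 (-4.33) of the shared markers fell. Cabp1 (3.44) of the channels and synapse genes and Fscn2 (2.88) of the mechanotransduction genes (list adjusted p = 0.22) rose. Supporting cell markers gave 4 of 16 lower and 1 higher, with Tecta (-4.29) and Epyc (-2.84) lower. For collagens the list test gave adjusted p = 6.81e-30 (adjusted p = 0.0377 with an estimated correlation), with 15 lower when adjusted over the list alone. For bone and cartilage the list test gave adjusted p = 1.70e-13 (adjusted p = 0.0429 with an estimated correlation), with 1 higher and 9 lower when adjusted over the list alone. For fetal growth genes the list test gave adjusted p = 4.60e-14 (adjusted p = 0.0429 with an estimated correlation), with 7 lower when adjusted over the list alone. For fibrocytes and mesenchyme the list test gave adjusted p = 7.19e-11 (adjusted p = 0.152 with an estimated correlation), with 1 higher and 8 lower when adjusted over the list alone. For spiral ganglion neurons the list test gave adjusted p = 6.96e-07 (adjusted p = 0.15 with an estimated correlation), with 9 higher when adjusted over the list alone. For interferon response genes the list test gave adjusted p = 7.81e-09 (adjusted p = 0.0429 with an estimated correlation), with 8 higher when adjusted over the list alone. For nuclear and untranslated RNAs the list test gave adjusted p = 1.21e-07 (adjusted p = 0.00248 with an estimated correlation), with 5 higher when adjusted over the list alone. With TMM scaling and an estimated correlation this list did not pass (adjusted p = 0.0668). For outer hair cell markers the list test gave adjusted p = 0.0421 (adjusted p = 0.702 with an estimated correlation), with 2 lower when adjusted over the list alone. For the shared markers the list test gave adjusted p = 0.0421 (adjusted p = 0.702 with an estimated correlation), with 1 lower when adjusted over the list alone. For channels and synapse the list test gave adjusted p = 0.017 (adjusted p = 0.623 with an estimated correlation), with 1 higher when adjusted over the list alone. For supporting cell markers the list test gave adjusted p = 0.0421 (adjusted p = 0.754 with an estimated correlation), with 3 higher and 5 lower when adjusted over the list alone. Schwann cell and muscle markers, with 1 gene each higher, erythroid markers, with 1 lower, and hair cell transcription factors also passed, at adjusted p = 0.00758 to 0.0457 (adjusted p = 0.623 to 0.754 with an estimated correlation). With TMM scaling the shared (adjusted p = 0.0948), supporting cell (0.106), erythroid (0.0685) and muscle lists (0.15) no longer passed.

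Whole cochlear RNA gave the background for these age changes. From P8 to 10 weeks in input, Slc4a11 rose from 3.13 ± 1.45 CPM (SD, n = 2) to 1595 ± 248 CPM (n = 3), a log2 change of 7.69 relative to all genes (limma adjusted p = 1.76e-17), with Ceacam16 (5.95), Ppp1r1a (5.31), the sodium channel subunit gene Scn4b (4.93) and Snap25 (4.83). Col2a1 fell from 7054 ± 7716 to 38.7 ± 0.827 CPM (-7.76, adjusted p = 5.32e-12), with Mir6236 (-8.63), Tectb (-7.72), Col9a1 (-7.03) and Tmprss9 (-6.79). Slc4a11, Ceacam16, Col2a1, Mir6236, Tectb and Tmprss9, among the largest changes in IP over this span, thus moved in the same direction in input. Mir6236 was at 486 ± 598 CPM in P8 input (SD, n = 2), so its fall in input rests on libraries that differed widely. Spiral ganglion neuron markers gave 9 of 12 higher, Schwann cell and myelin markers 8 of 11, interferon response genes 7 of 10 and mitochondrially encoded mRNAs 7 of 9. Collagens gave 9 of 15 lower, and bone and cartilage markers 4 of 12 lower and 1 higher. For spiral ganglion neurons the list test gave adjusted p = 6.94e-17 (adjusted p = 0.0236 with an estimated correlation), with 9 higher when adjusted over the list alone. For Schwann cells the list test gave adjusted p = 1.06e-06 (adjusted p = 0.271 with an estimated correlation), with 11 higher when adjusted over the list alone. For interferon response genes the list test gave adjusted p = 7.61e-08 (adjusted p = 0.0642 with an estimated correlation), with 10 higher when adjusted over the list alone. For mitochondrially encoded mRNAs the list test gave adjusted p = 6.30e-05 (adjusted p = 0.271 with an estimated correlation), with 8 higher when adjusted over the list alone. For collagens the list test gave adjusted p = 1.69e-50 (adjusted p = 0.01 with an estimated correlation), with 15 lower when adjusted over the list alone. For bone and cartilage the list test gave adjusted p = 3.33e-15 (adjusted p = 0.0488 with an estimated correlation), with 1 higher and 4 lower when adjusted over the list alone. Another 10 lists passed with the preset correlation, at adjusted p = 2.13e-10 to 0.0289, and not with an estimated one (adjusted p = 0.189 to 0.664 with an estimated correlation). Of these, calcium buffering, oxidative phosphorylation, stria vascularis, neutrophil, muscle, oxidative stress and channels and synapse genes moved up, and fibrocyte, fetal growth and cell cycle genes moved down. With TMM scaling the oxidative stress list no longer passed (adjusted p = 0.341). Rpl22 was at 47.2 ± 54.5 and 113 ± 7.21 CPM, a log2 change as deposited of 1.97 (SE 0.64, adjusted p = 0.0373), which did not pass with TMM scaling (0.58, adjusted p = 0.301). Slc26a5 was at 1.92 ± 2.06 and 6.40 ± 0.418 CPM (0.60, adjusted p = 0.248) and Ikzf2 at 6.998 ± 6.17 and 9.33 ± 1.35 CPM (-0.33, adjusted p = 0.574). As deposited, 1829 genes were higher and 70 lower with a median gene 0.94 higher at 10 weeks, and with TMM scaling 719 were higher and 492 lower. The number called was 825 without 10wk input 1, 837 without 10wk input 2, 817 without 10wk input 3, 9588 without P8 input 1 and 531 without P8 input 2. In input limma called 59 in a fit of only the libraries compared, 1072 without a filter, 1088 with the replicate block and 980 with the block and TMM scaling. More genes were lower than higher with only the libraries compared (27 and 32).

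The change of enrichment asks whether age acted differently in IP and in input. Enrichment fell for 6 genes between P8 and 10 weeks. Ubtf (chromosome 11, 102304560 to 102319742) was at 1333 ± 444 CPM in IP and 60.6 ± 68.5 CPM in input at P8 (SD, n = 2 each), and at 91.3 ± 24.7 and 103 ± 5.44 CPM at 10 weeks (n = 3 each). Its log2 change was -4.30 relative to all genes (limma adjusted p = 0.000915). Zbtb7a, a transcriptional repressor, was at 858 ± 74.3 and 39.1 ± 44.3 CPM at P8 and 95.8 ± 41.3 and 80.7 ± 6.72 CPM at 10 weeks (-3.97, adjusted p = 0.00386). The guidance cue Sema7a fell as well (-3.48, adjusted p = 0.0266). The predicted RNAs Gm27483 (-4.52, adjusted p = 0.0304; with TMM scaling 0.0785) and Gm27786 (-4.15, adjusted p = 0.000915) lie within H19 on the opposite strand, and whether the counting used strand is not stated; they fall outside the naming rule and were named after their values were seen. Slc26a5 (0.19, adjusted p = 0.741), Rpl22 (-1.53, 0.173) and Ikzf2 (-0.45, 0.413) did not pass. By limma 0 genes rose and 6 fell, with 3361 genes at an unadjusted p under 0.05 in either direction and a median gene at -1.0. TMM scaling called 6 higher and 31 lower, edgeR 4 and 15, and DESeq2 223 and 171. Nuclear and untranslated RNAs moved up as a list (2.41 relative to all genes; adjusted p = 7.13e-05, and adjusted p = 0.0107 with an estimated correlation), with 1 higher when adjusted over the list alone; with TMM scaling and an estimated correlation it did not pass (adjusted p = 0.137). Calcium buffering (-1.12), oxidative phosphorylation (-0.88), fetal growth (-1.42), stria vascularis (-1.02) and spiral ganglion neuron lists (-1.05) moved down at adjusted p = 0.000114 to 0.00931 (adjusted p = 0.85 with an estimated correlation for all 5). Adjusted over the list alone, 8, 0, 6, 3 and 6 of their genes were lower. With TMM scaling the fetal growth (adjusted p = 0.0532) and neuron lists (0.0632) no longer passed. Leaving out libraries in turn, the test called 3 without 10wk input 1, 2 without 10wk IP 1, 3 without 10wk input 2, 3 without 10wk input 3, 8125 without P8 input 1, 2 without P8 IP 1 and 2 without P8 IP 2. The total came to 1 in a fit of only the libraries compared and 98 without a filter. More genes were higher than lower with no filter (51 and 47) and DESeq2 (223 and 171).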

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

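The test of the totals of P8 input replicate 2 and the test of nuclear RNA were chosen after the results were seen. Enrichment in IP differed between P8 and 10 weeks, by the interaction term of the limma model, for 6 genes, 5 of which are given here. On the log2(CPM + 1) scale as deposited the differences were -5.51 for Gm27483, -5.30 for Ubtf, -5.14 for Gm27786, -4.96 for Zbtb7a and -4.48 for Sema7a, where the median gene stood at -1.0. Gm27786 had no reads at 10 weeks in either fraction, so that its value depends on the pseudocount. Sema7a went from 330.5 ± 153 CPM in IP and 16.7 ± 18.0 CPM in input at P8 to 213 ± 116 and 163 ± 24.4 CPM at 10 weeks (SD, n = 2 each at P8 and 3 each at 10 weeks).

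P8 input replicate 2 had a median gene at 0.117 times the value in replicate 1, and it enters the P8, input and interaction comparisons. Gm42418 reads in the CPM total are argued against as the whole cause, since the ratio was 0.137 with them out of both totals. With the reads aligned to several places out as well it was 0.2769, and since the files do not show which reads outside genes or in other genes come from ribosomal RNA, this and other causes cannot be told apart. With TMM scaling Ubtf kept a difference of -3.81 (limma adjusted p = 0.000511), Zbtb7a -3.5 (0.00491), Sema7a -3.08 (0.0168) and Gm27786 -4.57 (0.0161), so for these 4 the scaling alone did not remove the difference. Gm27483 no longer passed (-4.59, adjusted p = 0.0785). A biological change of their translation with age stays open and was not tested further.

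Reads outside annotated genes, which no comparison of genes uses, averaged 32.9% in IP and 13.3% in input. Genomic DNA spread evenly over the genome is argued against, since the exons of 1134 olfactory receptor genes held 0.0740 of the reads that such an excess would bring. Nuclear RNA carried into the IP libraries may contribute, since the fixed list of nuclear and untranslated RNAs had a median enrichment of 1.43 relative to all genes. The files hold no intron counts, which would test this further. No biological explanation was tested.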

How the results depend on the processing

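Values cover log2 changes as deposited, 357 in all, of which 327 were called. They are those of genes ranked by the naming rule, of Slc26a5, Rpl22 and Ikzf2, and of some list members. From each list only the called members with the largest changes were taken, and those with smaller changes were not tried. List members were taken for IP against input over all ages, IP and input at 10 weeks against P8 and the change of enrichment. None of the 327 changed direction under the alternatives tried. Those that used all libraries kept between 258 (no filter) and 315 (pseudocount of 0.25) past the threshold, TMM scaling 300, DESeq2 307 and edgeR 287. Leaving out the low-yield libraries kept 279 (288 with TMM scaling), removing mitochondrial and haemoglobin genes 303 of 303 still tested, and a fit of only the libraries compared 74 of 210; with 1 library left out 3280 of 3592 values kept it. The 56 reversed values all belong to Slc26a5, Rpl22 and Ikzf2 in comparisons where they were not called, and none was called after reversing. The alternatives gene reads only, low-yield libraries left out and those joining TMM scaling with another choice were chosen after the data were seen. At 10 weeks, with 3 libraries per fraction, the simulation recovered 14% of 2-fold and 92% of 4-fold changes; for IP at 10 weeks against P8, with 3 and 2 libraries, it recovered 12% and 82%. IP against input at the ages with 2 per fraction was not simulated, nor were libraries that stand apart, such as P8 input replicate 2. Of 100 splits of the libraries within ages, the real one included, only the real one gave 6087 genes over all ages. The highest other gave 959. The 100 are a sample of the possible splits, and others can mix IP and input within a group, which widens the spread. The share was thus 1 in 100, which does not exclude chance. At 10 weeks the 10 possible splits are too few for a share under 0.05; the real one gave 789 and the highest other 7. A group left with 1 library is assumed to vary like the others.

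Counts of called genes moved by over 1.5 times as follows; a count for one age is IP against input. With a pseudocount of 0.25 they were 428 (P14), 497 (10wk), 138 (IP P14 against P8) and 913 (IP 10wk against P28). Without a filter they were 1298 (P8), 94 (P14), 387 (P28), 146 (6wk), 174 (IP P14 against P8), 38 (IP P28 against P14), 1072 (input 10wk against P8), 98 (the change of enrichment), 7 (genes higher at all ages) and 0 (genes lower at all ages). TMM scaling gave 3514 (P14), 4205 (P28), 1612 (6wk), 2983 (10wk), 1564 (IP P14 against P8), 1214 (IP P28 against P14), 1297 (IP 10wk against P28), 2137 (IP 10wk against P8), 1211 (input 10wk against P8), 37 (the change of enrichment), 288 (genes higher at all ages) and 356 (genes lower at all ages). Quantile normalization gave 3601 (P14), 4173 (P28), 2513 (6wk), 4151 (10wk), 1438 (IP P14 against P8), 724 (IP P28 against P14), 1158 (IP 10wk against P28), 3110 (IP 10wk against P8), 57 (the change of enrichment), 397 (genes higher at all ages) and 601 (genes lower at all ages). Without mitochondrial and haemoglobin genes, which takes both mitochondrial ribosomal RNAs out of the test, the genes lower at all ages came to 0. limma fits of only the libraries compared, whose error estimates rest on those libraries alone, gave 0 (P8), 0 (P14), 0 (P28), 1975 (6wk), 7503 (10wk), 0 (IP P14 against P8), 0 (IP P28 against P14), 0 (IP 10wk against P28), 1381 (IP 10wk against P8), 59 (input 10wk against P8), 1 (the change of enrichment), 0 (genes higher at all ages) and 0 (genes lower at all ages). CPM over gene reads gave 1494 (P14), 2450 (P28), 622 (6wk), 1902 (10wk), 294 (IP P28 against P14), 1247 (IP 10wk against P28), 1535 (IP 10wk against P8), 1263 (input 10wk against P8), 2 (the change of enrichment), 238 (genes higher at all ages) and 18 (genes lower at all ages). Leaving out the low-yield libraries gave 2584 (P14), 4123 (P28), 2816 (6wk), 4571 (10wk), 1063 (IP P14 against P8), 54 (IP P28 against P14), 3767 (IP 10wk against P8), 946 (input 10wk against P8), 166 (genes higher at all ages) and 356 (genes lower at all ages), and with TMM scaling 9452 (IP against input over all ages), 3486 (P14), 5133 (P28), 3114 (6wk), 5033 (10wk), 1420 (IP P14 against P8), 850 (IP 10wk against P28), 4330 (IP 10wk against P8), 1196 (input 10wk against P8), 73 (the change of enrichment), 299 (genes higher at all ages) and 642 (genes lower at all ages). edgeR gave 2566 (P14), 3276 (P28), 1443 (6wk), 2356 (10wk), 973 (IP P14 against P8), 414 (IP P28 against P14), 660 (IP 10wk against P28), 1429 (IP 10wk against P8), 901 (input 10wk against P8), 19 (the change of enrichment), 301 (genes higher at all ages) and 284 (genes lower at all ages). DESeq2 gave 4156 (P14), 6042 (P28), 2398 (6wk), 3305 (10wk), 2362 (IP P14 against P8), 2383 (IP P28 against P14), 2641 (IP 10wk against P28), 3132 (IP 10wk against P8), 394 (the change of enrichment), 519 (genes higher at all ages) and 450 (genes lower at all ages). Leaving out each library in turn gave 489 to 8746 (P8), 19 to 1206 (P14), 669 to 2798 (P28), 15 to 59 (6wk), 96 to 340 (10wk), 47 to 925 (IP P14 against P8), 13 to 1535 (IP P28 against P14), 50 to 2369 (IP 10wk against P28), 137 to 573 (IP 10wk against P8), 531 to 9588 (input 10wk against P8), 2 to 8125 (the change of enrichment), 5 to 260 (genes higher at all ages) and 0 to 173 (genes lower at all ages). Apart from the removal of mitochondrial genes, the causes were not tested.

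The replicate numbers of IP and input neither showed nor excluded pairing: the correlations of their deviations from the group means ran from 0.0417 to 0.343, over 0.1 at 6 and 10 weeks and under it at P8, P14 and P28. The replicate block moved the counts to 173 (IP 10wk against P28) and 1088 (input 10wk against P8), and changed no other count by over 1.5 times; TMM scaling with the block gave 3653 (P14), 4399 (P28), 1707 (6wk), 3092 (10wk), 1369 (IP P14 against P8), 1117 (IP P28 against P14), 654 (IP 10wk against P28), 1684 (IP 10wk against P8), 980 (input 10wk against P8), 16 (the change of enrichment), 313 (genes higher at all ages) and 405 (genes lower at all ages). With TMM scaling, 20 lists were called over all ages and 5 for the change of enrichment. It gave 12 for IP 10wk against P8 and 16 for input 10wk against P8. Since lists named above dropped out in each comparison, these include lists that did not pass as deposited. As deposited, 19 lists were called over all ages and 15 for IP 10wk against P8. For input 10wk against P8 there were 16 and for the change of enrichment 6. With an estimated correlation these were 1 over all ages, 5 for IP 10wk against P8, 3 for input 10wk against P8 and 1 for the change of enrichment, with TMM scaling and an estimated correlation 5 over all ages, 5 for IP 10wk against P8, 6 for input 10wk against P8 and 0 for the change of enrichment, and with fry, which does not compare a list with other genes, 7 for IP 10wk against P8 and 2 for the change of enrichment. The cause was not tested.

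For Rpl22, IP against input at P8, the log2 change of 0.88 became -0.518 (TMM), -0.698 (quantile), -0.518 (TMM with the block), -0.706 (low-yield libraries out), -0.694 (TMM and low-yield libraries out), -0.532 (edgeR) and -0.531 (DESeq2), with 1 library left out -0.706 to 2.46. For Slc26a5, IP against input at P14, the log2 change of -0.48 became 0.278 (quantile), 0.162 (low-yield libraries out) and 0.178 (TMM and low-yield libraries out), with 1 library left out -1.13 to 0.162. For Slc26a5, IP against input at P28, the log2 change of 0.10 became -0.386 (edgeR) and -0.323 (DESeq2), with 1 library left out -1.47 to 1.67. For Slc26a5, IP against input at 6wk, the log2 change of -0.42 became 0.0335 (edgeR) and 0.103 (DESeq2), with 1 library left out -2.19 to 1.36. For Ikzf2, IP P14 against P8, the log2 change of -0.23 became 0.5001 (TMM), 0.229 (quantile), 0.5001 (TMM with the block), 0.129 (gene reads only), 0.157 (low-yield libraries out), 0.373 (TMM and low-yield libraries out), 0.503 (edgeR) and 0.392 (DESeq2), with 1 library left out -0.609 to 0.157. For Slc26a5, IP P28 against P14, the log2 change of 0.46 changed sign, with 1 library left out -0.211 to 1.13. For Rpl22, IP P28 against P14, the log2 change of 0.35 became -0.161 (low-yield libraries out) and -0.0189 (TMM and low-yield libraries out). For Ikzf2, IP P28 against P14, the log2 change of -0.43 changed sign, with 1 library left out -0.970 to 0.107. For Rpl22, IP 10wk against P28, the log2 change of -0.10 became 0.133 (low-yield libraries out), with 1 library left out -0.329 to 0.133. For Ikzf2, IP 10wk against P28, the log2 change of -0.17 became 0.365 (low-yield libraries out) and 0.0726 (TMM and low-yield libraries out), with 1 library left out -0.713 to 0.365. For Ikzf2, input 10wk against P8, the log2 change of 0.61 became -0.640 (TMM), -0.662 (quantile), -0.667 (TMM with the block), -0.269 (low-yield libraries out), -0.245 (TMM and low-yield libraries out), -0.754 (edgeR) and -0.812 (DESeq2), with 1 library left out -0.269 to 1.498. For Slc26a5, the change of enrichment, the log2 change of -0.81 became 0.0961 (TMM), 0.205 (quantile), 0.0961 (TMM with the block), 0.0356 (TMM and low-yield libraries out), 0.0649 (edgeR) and 0.224 (DESeq2). For Ikzf2, the change of enrichment, the log2 change of -1.45 became 0.123 (quantile), 0.0213 (edgeR) and 0.176 (DESeq2). The cause was not tested.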

Other observations

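The table of microRNA families and the test of nuclear RNA against the let-7 result were chosen after that result was seen, as was the reading of the test per immunoprecipitate and age. Several other gene groups were measured in IP against input over all ages. Immediate early and heat shock genes went both ways, with Dusp1 (2.5) and Ier2 (2.49) higher in IP relative to all genes and the chaperone Hspa8 (-1.89) lower, and the list, with 5 of 12 higher and 2 lower, did not pass limma's camera test (adjusted p = 0.481; 5 higher and 2 lower when adjusted over the list alone). Endothelial markers gave 3 of 8 higher and 1 lower, with Egfl7 (1.38) and Emcn (-1.27), and did not pass (adjusted p = 0.677; 4 higher and 1 lower when adjusted over the list alone). Skeletal muscle markers gave 3 of 10 lower, such as Mylpf (-1.27; list adjusted p = 0.0512; 3 lower when adjusted over the list alone). Collagens gave 4 of 15 higher and 1 lower, with Col11a2 (1.52) higher (list adjusted p = 0.279; 4 higher and 1 lower when adjusted over the list alone). B and T lymphocyte markers (adjusted p = 0.507; 0 called when adjusted over the list alone), with Cd79a lower (-0.85), and cell cycle genes (adjusted p = 0.37; 0 called when adjusted over the list alone) did not pass.

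Genes with a seed match for let-7, a microRNA family of differentiated tissues, were frequent among the RNAs enriched in IP. Of 14693 genes with a 3' untranslated region searched, 2516 (17.1%) held a match, against 15 of the 20 most enriched genes (75.0%), 62 of the top 100 and 251 of the top 500. A match was found in 25 of 37 searched genes among those called higher at all 5 ages, in 7 of 9 searched among the 10 genes named as highest and in 0 of 7 among the 10 named as lowest. Ikzf2 held 2 matches, and Ocm, Slc26a5 and Rpl22 held 0 each. Of 14695 heptamers ranked, the let-7 matches CTACCTC and TACCTCA were at ranks 1 and 4, the matches for miR-30 at 2 and 3, for miR-29 at 5 and 9 and for miR-26 at 6 and 7. Those for miR-183, miR-96 and miR-182, microRNAs of hair cells, were at 178 to 5694.

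Length and GC content of the 3' untranslated region and expression level are argued against as the whole cause, since with these in the model genes with a let-7 match stood 0.3952 higher in IP on the log2 scale (SE 0.0194; without them 0.6075), and so is any frequent heptamer, since the best let-7 match had rank 1. The bound written beforehand against 1 immunoprecipitate or 1 age as the cause, a difference over 0.1 in each of 11 pairs, was missed by 1 pair (0.0698, 10wk replicate 1), but 10 pairs and all 5 ages passed it, and reading this as evidence against that cause was decided after the result. Over 11 pairs by replicate number, a pairing without clear evidence, the adjusted let-7 coefficient fell as the excess of reads outside genes rose (Pearson r = -0.678, permutation p = 0.0213; Spearman rho = -0.782, p = 0.00642; r = -0.841 without P8 2 and 10wk 1), against what nuclear RNA as the cause would bring. Nuclear RNA stays open, since ages differ in such reads and within ages this fall did not pass (r = -0.586, exact p = 0.146 over 96 arrangements; rho = -0.6, p = 0.156). Translation in outer hair cells and RNA bound to microRNA complexes and pulled down with them cannot be told apart, since markers of other cell types with a match stood 0.283 above those without one (18 and 119 genes, permutation p = 0.303), and co-purification may be one explanation, as a hypothesis that an immunoprecipitate from cochleae without the tag, not analysed here, would test.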
